A study of Rattus norvegicus with 18 samples.

How the data were processed

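Messenger RNA of kidney tissue was sequenced in 18 libraries, 6 each of control animals (Ctrl), of a diabetic nephropathy model made with a high-fat diet and STZ (DN), and of model animals given TSK (Treat). Per the labels' protocols, RNA was harvested with a Qiagen column kit, and libraries were built from 1.3 µg of total RNA with a SMARTER mRNA kit. The authors deposited a table of raw counts per gene, with 1 column per library and no normalization. The aligner, the counter, the annotation release and the strand setting are not given in the sources used here. Per the submitters' processing notes, the genome builds were GRCm38 and mm10, which are mouse builds, while the labels give the organism as rat. The identifiers alone do not settle whether the animals were rats counted on a mouse reference or mice. If they were rats, reads that differ from the mouse sequence could have been lost unevenly between genes, and levels of different genes cannot be compared on that account.

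Columns were assigned to samples by the library names in the labels, and the group and replicate number of each sample came from its title. The rat gene table used here (0 of the 55335 identifiers matched) gives no names for them. The 51 gene lists fixed before the data were examined hold 979 symbols, 924 of which are in that table and 0 of which could be matched to an identifier, so none of these lists could be tested. The shares of mitochondrial and haemoglobin transcripts were not computed for the same reason. The rule for named genes, fixed at the same time, took per comparison the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 5 CPM in the higher group, and at least 5 of its 6 libraries above the median of the other group, with up to 4 further members per gene list. Without names no gene meets its symbol condition. The printed identifiers are the first 2 per direction under the rule without that condition (2271 genes higher and 2480 lower met it for DN versus Ctrl, 81 and 148 for Treat versus DN), a choice made after the values had been seen.

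Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (19233 genes), libraries were scaled with TMM factors, and all 18 libraries were fitted together with 1 coefficient per group and no covariate. The 3 comparisons were tested with the quasi-likelihood F-test (glmQLFit, glmQLFTest), and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the F statistics. CPM values use TMM-scaled library totals, and log2 CPM used a prior count of 2. Fold changes against a group without counts are lower bounds from a floor of 3 counts over the 6 libraries of that group, and they cover counting error only. The common biological coefficient of variation was 0.273. Library totals of 22040987 to 35275498 counts make sampling noise small beside the spread between animals for genes above a few CPM. Library measures were compared with two-sided exact permutation tests of the difference of means over all 924 splits, adjusted over 12 tests.

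The relation between the DN effect and the treatment effect was measured by the overlap of calls and by the slope of the Treat minus DN difference on the DN minus Ctrl difference in mean log2 CPM. For the slope, the DN libraries were divided in all 20 ways into 2 sets of 3. Genes were chosen with limma 3.58.1 (limma-trend on log2 CPM) in the first set against Ctrl, and the second set entered the treatment difference. Covariances of fold changes expected without a treatment effect, or without any effect, were simulated 20 times each from the fitted means and dispersions. Each gene and library was drawn independently. Cell-cycle lists were derived from the marker pairs installed with scran 1.30.0: a gene entered a phase list when it came first in a net share of at least 0.8 of its pairs in that phase and -0.5 or lower in another, with at least 10 pairs. They were tested with camera (preset correlation 0.01) and fry.

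Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no filter, a filter of CPM above 1 in at least 6 libraries, fits of only the 12 libraries compared, the replicate number as a block, limma voom with library quality weights, a minimum change of 2-fold, and each library left out in turn. Added after the data had been seen were library totals without scaling factors, counts thinned to the smallest library, leaving out control library 4 with treated library 1 or with control library 5, the all-or-none division of the controls as a covariate, removal of 1 member of each pair of identifiers with near-identical counts, and the cell-cycle lists. Such pairs numbered 7 among 14440 identifiers with a mean count of at least 50 (counts within 3% in every library), and their second members held 2.14% to 3.21% of a library's counts. The values of such genes are uncertain, since the counting could have used the same reads for both.

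The procedures were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 of 19233 genes changed per comparison. For DN versus Ctrl, edgeR recovered 26.9% of 67 genes changed 1.5-fold, 74.6% of 67 changed 2-fold and 86.4% of 66 changed 4-fold, with 5 false calls. For Treat versus DN the shares were 44.8%, 70.1% and 95.5%, with 10 false calls, and for Treat versus Ctrl 35.8%, 59.7% and 87.9%, with 8 false calls. In the real data 32.2% of the genes were called for DN versus Ctrl and 44.9% for Treat versus Ctrl. The adjustment is less strict when so many genes change, so the simulated shares do not carry over to these 2 comparisons. For simulated slopes of 0.1, 0 and -0.3 the procedure gave 0.0752, -0.0017 and -0.242. In this simulation slopes other than 0 thus came out nearer 0 than they were set, and the cause was not tested. Figures were drawn with matplotlib 3.10.9.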

Results

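Kidney transcriptomes were profiled by sequencing of polyadenylated RNA in 18 animals that the labels describe as Rattus norvegicus. The 3 groups held 6 libraries each, 1 per animal according to the series description. Control animals (Ctrl) received ordinary feed and were gavaged with the solvent. Animals of the diabetic nephropathy model (DN) were fed a high-fat diet and injected with STZ. The treated animals (Treat) were model animals that received TSK, a preparation the labels name only by this abbreviation, by mouth at 500 mg/kg per day over 4 weeks. Total counts per library ranged from 22040987 to 35275498. They averaged 29821958 ± 2834050 in Ctrl, 30484723 ± 3471181 in DN and 25560539 ± 2319368 in Treat (SD, n = 6 each). The treated libraries were shallower than the DN libraries (two-sided exact permutation test, p = 0.013, 0.0312 after Benjamini-Hochberg adjustment over 12 tests of library measures). All 55335 gene identifiers in the count table start with ENSMUSG, and the genome builds in the submitters' processing notes are builds of the mouse genome, which differs from the labelled species. The files do not pair the identifiers with gene names. Genes are therefore described by number, direction and expression level, and at most 2 identifiers per direction are printed for a comparison.

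The libraries separated first into controls on one side and DN and treated libraries on the other. For 5 of the 6 controls an all-or-none division described below runs the same way. The separation can therefore not be assigned to model status alone. On the first principal component (40.5% of the variance of log2 CPM), the controls averaged -75.1 ± 9.88, the DN libraries 28.2 ± 7.26 and the treated libraries 46.8 ± 12.1 (SD, n = 6 each). The DN libraries differed from the controls (exact permutation test, p = 0.00216, the smallest value 6 against 6 libraries can give), and the treated libraries lay farther from the controls than the DN libraries did (exact p = 0.0108, adjusted 0.0216 over 6 tests of components). The second component (10.6%) set control library 4 (-54.2) and treated library 1 (-78.8) apart from the other libraries. The 10 most abundant genes took 21.1% ± 1.70 of the counts in DN and 18.3% ± 0.88 in Ctrl (exact p = 0.00216, adjusted 0.026). They took 19.3% ± 1.38 in Treat, which was not distinguishable from DN (exact p = 0.0671, adjusted 0.115). Within groups, Pearson correlations across genes between libraries lay between 0.939 and 0.983, and every pair of libraries of a group differed by more than sampling noise (lowest chi-square per degree of freedom, 12.5).

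**Figure D1:**
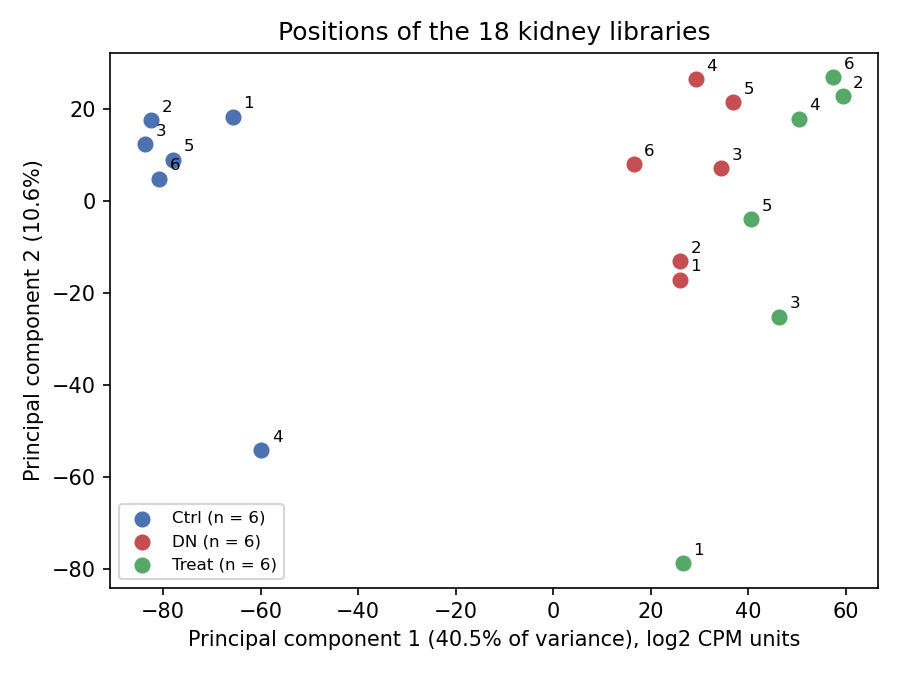
Principal component 1 (horizontal, 40.5% of the variance) against component 2 (vertical, 10.6%) of log2 CPM; each point is 1 of the 18 libraries, colored by group and numbered by replicate. The 6 control libraries lie at or below -59.8 on the horizontal axis and the 12 DN and treated libraries at or above 16.6, with control library 4 and treated library 1 low on the vertical axis.

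The comparison of DN with Ctrl asks what differed in the kidney of the model animals. Its calls cannot be assigned to the diet and STZ alone, because of the all-or-none division of the controls described below. Of 19233 genes tested, 3254 were higher and 2948 lower in DN, which is 32.2% of the genes. Changes of at least 2-fold were found for 1014 genes that rose and 710 that fell. The share of genes called grew with expression, from 15.3% of the genes under 1 CPM to 42.8% of the 1579 genes at 100 CPM or more. Among the called genes under 1 CPM, 68.8% were higher in DN, against 44.4% among those at 100 CPM or more. For 3127 genes (16.3%) the DN and control libraries did not overlap at all. Chance separates 0.216% of genes on average for 6 against 6 libraries, and more in some splits because genes vary together. ENSMUSG00000116207 had no count in any control library and stood at 69.3 ± 25.9 CPM in DN (SD, n = 6), which is at least 4054-fold higher (floor of 3 counts over the control group; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.77e-08). Its level in Treat was 62.8 ± 21.2 CPM (Treat versus DN, adjusted p = 0.876). ENSMUSG00000094075 likewise had no count in the controls and stood at 18.4 ± 29.9 CPM in DN, at least 1074-fold higher (adjusted p = 0.000392), with 78.9 CPM in DN library 4 and at most 10.5 CPM in the other DN libraries. Without that library it stood at 6.24 ± 3.82 CPM in DN (n = 5), at least 365-fold higher, and its log2 fold change was 10.46 (adjusted p = 0.0001), against 12.04 with it. Both identifiers had counts in every DN and treated library and in no control, control library 4 included. Whether the diet and STZ or another difference between these animals and the controls gave this was not tested.

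Of the 2 identifiers with the largest falls, ENSMUSG00000086503 fell from 1277 ± 634 CPM in Ctrl to 0.778 ± 0.351 CPM in DN (log2 fold change -10.67, SE 1.07, adjusted p = 1.18e-06). Its counts were 38313 to 52784 in 5 control libraries, 23 in control library 4, and 12 to 41 in all DN and treated libraries. Without control library 4 its log2 fold change was -10.94 (adjusted p = 9.6e-16). It was 1 of 25 identifiers for which the other 5 control libraries stood all-or-none apart from control library 4 and from every DN and treated library, 9 of them high and 16 low in those 5 controls. The same search gave 7, 0, 0, 2 and 0 identifiers when control library 1, 2, 3, 5 or 6 took the place of library 4. With this division of the controls as a covariate, which leaves control library 4 as the reference, 986 genes were called between DN and Ctrl (451 higher, 535 lower), and ENSMUSG00000086503 was no longer called (log2 fold change -0.11, SE 0.42, adjusted p = 0.911; range over its alternatives 2.8e-41 to 0.911). Since it is 1 of the identifiers that define the division, the loss of its call in this fit was fixed in advance and is no test. Its counts follow the division of the controls, and its fall cannot be assigned to the diet and STZ. ENSMUSG00000094075 was not called in that fit either (adjusted p = 0.139; range over its alternatives 9.05e-18 to 0.139), but its fitted log2 fold change was 12.04 in both fits and only its SE grew, from 1.92 to 4.54, with 1 control as the reference. ENSMUSG00000029368 fell from 1025 ± 2437 to 10.8 ± 1.96 CPM (log2 fold change -6.57, SE 1.47, adjusted p = 0.00237). Control library 5 held 5999.8 CPM of it and the other 5 controls 16.2 to 70.4 CPM, and without library 5 the log2 fold change was -1.47 (adjusted p = 0.00990; range over its alternatives 0.00161 to 0.387).

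**Figure D2:**
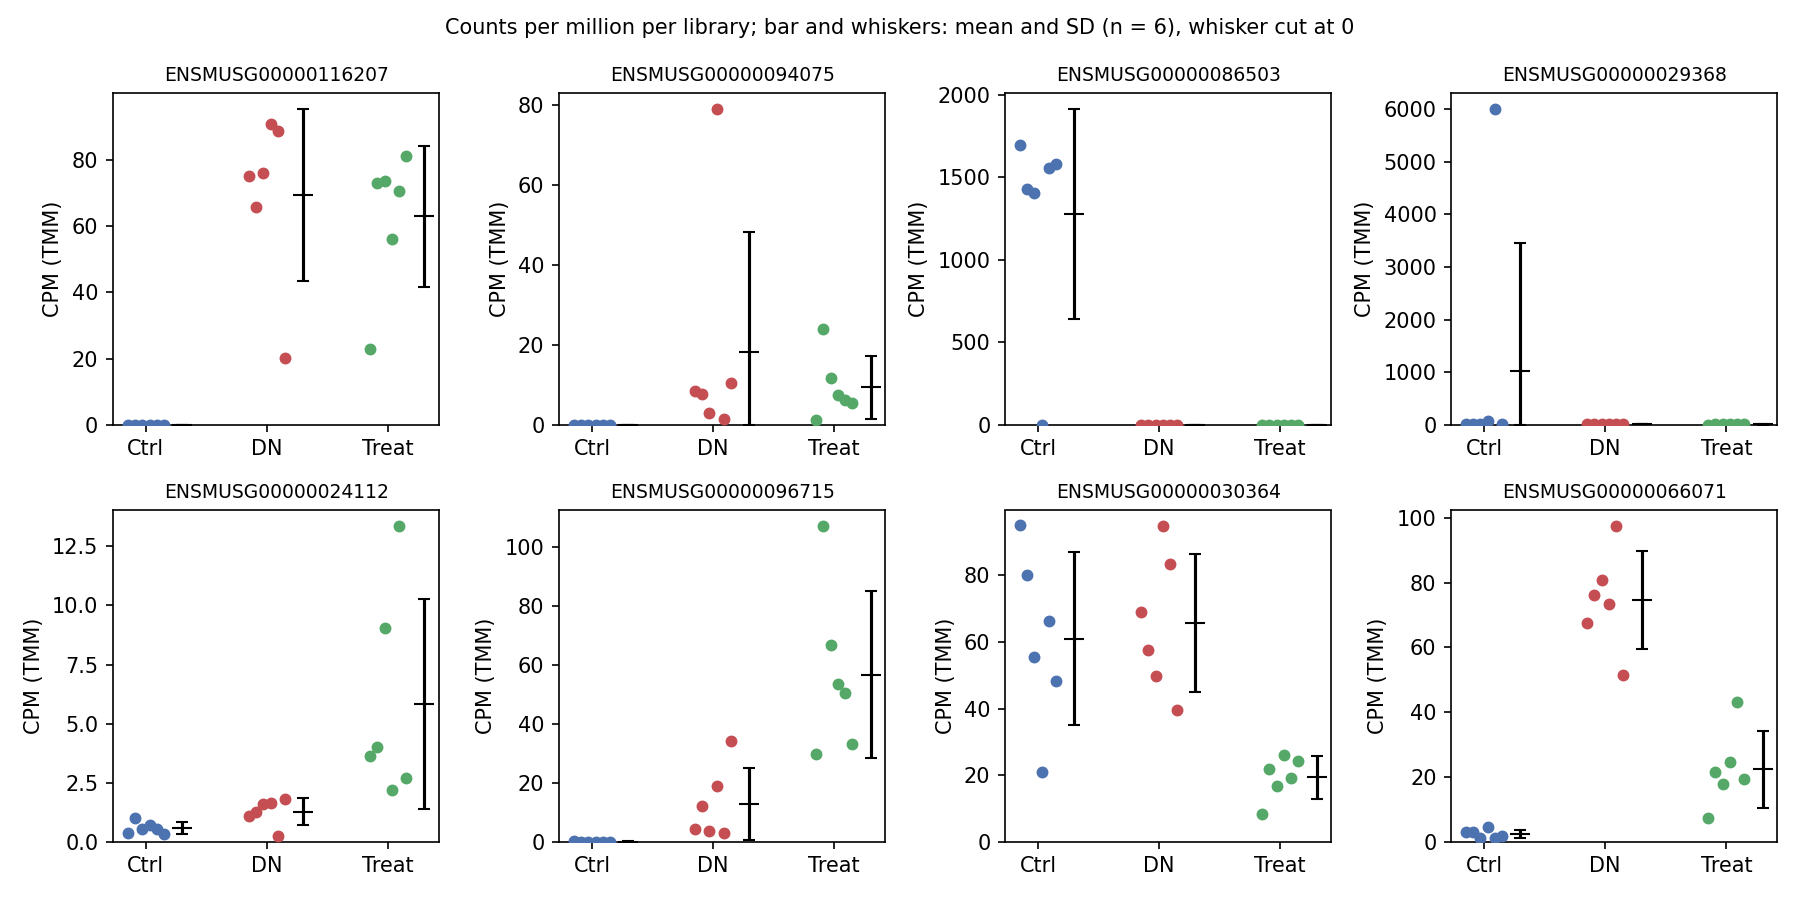
Scaled counts in CPM (vertical axes, linear, from 0) of the 8 printed identifiers in each library of the 3 groups; black bars give the mean and SD (n = 6), with the lower whisker ended at 0. The upper row holds the identifiers chosen for DN versus Ctrl, where ENSMUSG00000086503 is near 0 in control library 4, and the lower row those chosen for Treat versus DN, where ENSMUSG00000066071 averages 2.44, 74.5 and 22.4 CPM in Ctrl, DN and Treat.

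The comparison of Treat with DN asks what TSK changed in the diseased kidney. It called 268 genes (1.39%), 103 higher and 165 lower in Treat. Of these, 23 rose and 47 fell by at least 2-fold. By expression level, 43 genes were lower and 5 higher among 1579 at 100 CPM or more, 84 lower and 61 higher among 8227 from 10 CPM up to that level, 36 lower and 31 higher among 6066 from 1 to 10 CPM, and 2 lower and 6 higher among 3361 under 1 CPM. The treated and DN libraries did not overlap for 347 genes (1.80%). Chance separates 0.216% on average, but genes vary together, so a larger share can also arise by chance. An arbitrary split of these libraries called more genes than the real one, as given below. ENSMUSG00000066071 rose from 2.44 ± 1.33 CPM in Ctrl to 74.5 ± 15.1 CPM in DN and stood at 22.4 ± 11.8 CPM in Treat (Treat versus DN log2 fold change -1.74, SE 0.33, adjusted p = 0.015), with all 6 treated libraries below all 6 DN libraries. It remained above the controls (Treat versus Ctrl log2 fold change 3.19, adjusted p = 3.66e-06). ENSMUSG00000030364 stood at 65.7 ± 20.8 CPM in DN and fell to 19.4 ± 6.38 CPM in Treat (log2 fold change -1.76, SE 0.31, adjusted p = 0.00869). DN and Ctrl were not distinguishable for this gene (61.0 ± 25.9 CPM in Ctrl, adjusted p = 0.816). Both of these falls held in each of 29 alternative settings.

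Among the genes that rose under treatment, ENSMUSG00000024112 went from 1.28 ± 0.579 to 5.83 ± 4.43 CPM (log2 fold change 2.18, SE 0.46, adjusted p = 0.0258; 0.599 ± 0.252 CPM in Ctrl). ENSMUSG00000096715 went from 12.8 ± 12.2 to 56.7 ± 28.1 CPM (log2 fold change 2.15, SE 0.52, adjusted p = 0.0468) and was near 0 in Ctrl, where 1 library held 7 counts and the others none. The first lost its call in 7 and the second in 18 of 29 alternative settings, with adjusted p values of up to 0.113 and 0.0972. The number of genes called between Treat and DN moved by over 1.5 times when any of 8 of the 18 libraries was left out: it was 164 without control library 6, 152, 119, 97 and 125 without DN library 1, 2, 4 or 6, and 446, 119 and 160 without treated library 1, 3 or 6. The balance of directions depended on the scaling, since with library totals in place of TMM factors 654 genes were higher and 121 lower (84.4% higher, against 38.4%), with the median of all genes shifted by 0.13 on the log2 scale. The shift equals the log2 ratio of the groups' TMM factors (0.13), which averaged 1.057 in Treat and 0.964 in DN (exact p = 0.00433, adjusted 0.026 over 12 tests).

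Of 142 genes called in DN versus Ctrl and in Treat versus DN, 90 went the same way in both (24 higher, 66 lower) and 52 the opposite way (28 higher in DN and lowered by treatment, 24 lower in DN and raised). Independent lists of these sizes would share 42.7 genes in the same and 43.7 in the opposite direction. Both comparisons use the DN libraries, which by itself favors opposite signs: with a treated group simulated as unchanged from DN (20 simulations), the covariance of the fold changes across genes was -0.0416, against an observed 0.0266. These simulations called no gene between Treat and DN and so give no reference for the counts. With the DN libraries divided into 2 sets of 3, so that the comparisons shared none of them, the median over 20 divisions was 0 genes called between Treat and DN (0 to 471). With so few calls these divisions cannot test the counts of 90 and 52 without shared libraries. The difference of the observed and simulated covariances was 0.0682, and the correlation across genes, which are not independent replicates, was 0.0923 observed and -0.183 simulated. Each gene was simulated independently, so variation that genes share between libraries is missing. The difference therefore does not by itself show an effect along the DN direction. With single libraries left out, the counts ranged from 42 to 162 in the same and from 18 to 78 in the opposite direction, and the former was the larger in 30 of 30 alternative settings, by as little as 36 against 35 with only the libraries compared in each fit. The other 126 treatment calls (55 higher, 71 lower) were not called between DN and Ctrl.

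**Figure D3:**
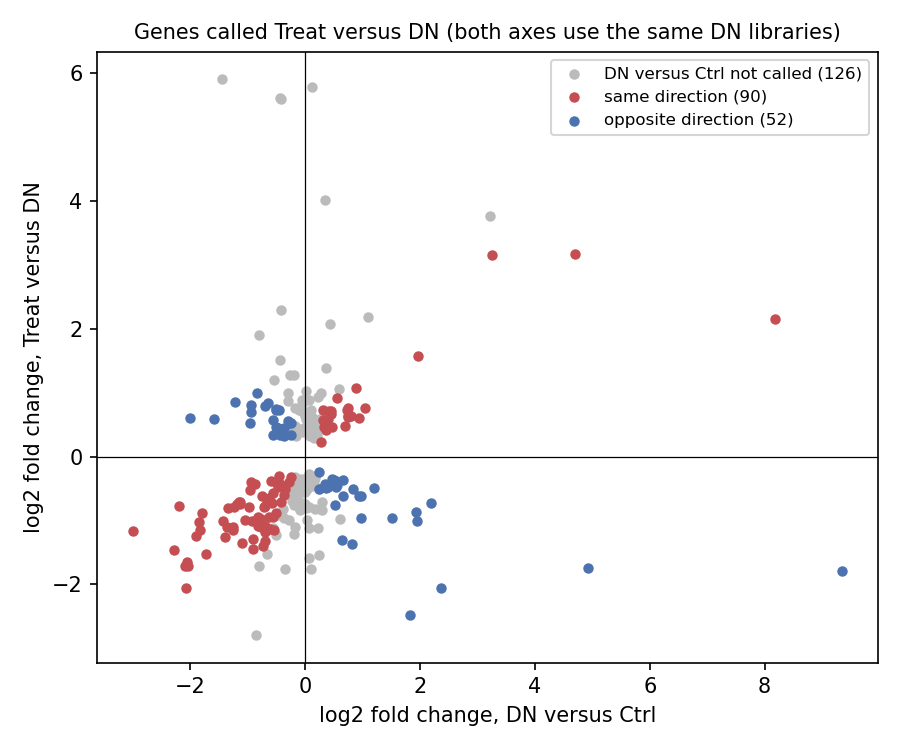
Log2 fold change of DN versus Ctrl (horizontal) against that of Treat versus DN (vertical) for the 268 genes called between Treat and DN; each point is a gene, and both axes use the same DN libraries. Of the genes also called between DN and Ctrl, 90 lie in the quadrants of equal sign and 52 in those of opposite sign.

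With these divisions, in which no DN library entered both differences, the Treat minus DN difference still rose with the DN minus Ctrl difference across the genes called in the first set. The slope averaged 0.0958 and was 0.0544 to 0.155 over the 20 ways to divide the libraries. Genes lower in DN had a median change of -0.14 (log2) under treatment, averaged over the divisions, and genes higher in DN one of 0.03. The ranges of both over the divisions included 0 (-0.29 to 0.0017 and -0.06 to 0.16), and neither was larger than about the shift of 0.13 between scalings. A score of each library along the model's direction averaged 0.999 in Treat and 0.906 in the DN libraries held out (Ctrl at 0, the DN libraries that set the scale at 1). The mean score of the treated libraries was above that of the held-out DN libraries in all 20 divisions, which reuse the same libraries and are not independent. The exact permutation test of 6 against 3 libraries fell below 0.05 in 1 of 20 (exact p from 0.0357 to 0.464, smallest possible 0.0119). On the first principal component, an axis that all 18 libraries set, the test of 6 against 6 libraries did pass (adjusted p = 0.0216, above). Without treated library 1 the slope was 0.131.

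The comparison of Treat with Ctrl asks what still set the treated animals apart from the control animals. It called 8629 genes (44.9%), 4415 higher and 4214 lower, of which 1361 and 1080 changed by at least 2-fold. Of the genes higher in DN, 85.5% (2781 of 3254) were also called higher in Treat, and of the genes lower in DN, 85.0% (2505 of 2948) were also called lower. Opposite calls numbered 5. The median log2 fold change against Ctrl of the genes higher in DN was 0.66 in DN and 0.67 in Treat, and that of the genes lower in DN was -0.58 in DN and -0.65 in Treat. Both comparisons share the controls. Independent lists would agree in direction for 1393 genes. With the controls divided into 2 sets of 3, a median of 2419 genes were called in the same direction (2190 to 2664 over 20 divisions; 580 expected of independent lists) and 3.5 in opposite directions (0 to 10). These sets do not remove the all-or-none division: each holds at least 2 of the 5 controls that stand apart from all DN and treated libraries, so agreement in direction can also arise from that difference. The covariance of the fold changes across genes was 0.6253, against 0.0401 with both groups simulated as unchanged from control, a difference of 0.585. The simulated libraries hold neither the variation that genes share nor the all-or-none division. This difference can therefore not be assigned to the model. With the all-or-none division of the controls as a covariate, 1862 genes were called between Treat and Ctrl (750 higher, 1112 lower). With library totals in place of TMM factors 64.5% of the calls were higher, against 51.2%, with the median of all genes shifted by 0.10 on the log2 scale (TMM factors 1.057 in Treat and 0.983 in Ctrl, adjusted p = 0.0312).

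Genes marking the phases of the cell cycle were the only lists that could be matched to the identifiers, and they were chosen after the identifiers had been seen. They were learned on mouse embryonic stem cells, so that their members need not track the cycle in kidney. Of 127 measured genes of the G1 list, 18 were higher and 50 lower in Treat than in Ctrl, over all genes tested and likewise when adjusted over the list alone (camera, adjusted p = 0.0199 over 3 lists; adjusted p = 0.43 with an estimated correlation; fry, adjusted p = 0.000183). Without control library 4 this list was no longer called (adjusted p = 0.0832). In DN versus Ctrl, 11 of its genes were higher and 41 lower (13 and 45 when adjusted over the list alone; camera, adjusted p = 0.0575; adjusted p = 0.612 with an estimated correlation; fry, adjusted p = 0.00722). The S list held 10 higher and 10 lower genes among 82 in DN versus Ctrl and 17 and 17 in Treat versus Ctrl. The G2M list held 7 and 5 among 78 in DN versus Ctrl and 12 and 9 in Treat versus Ctrl. Neither was called by camera in any comparison (lowest adjusted p = 0.52). For the G2M list these counts depended on control library 4, whose mean log2 CPM over the list was 3.25, against 2.18 to 2.36 in the other controls and 2.41 to 2.60 in DN. Without that library the G2M list held 18 higher and 6 lower genes among 79 in DN versus Ctrl (camera, adjusted p = 0.119) and 19 and 8 in Treat versus Ctrl (adjusted p = 0.421). Between Treat and DN the 3 lists together had 2 higher and 3 lower genes, and none was called by camera or by fry's directional test (lowest adjusted p = 0.311 and 0.247). Fry's mixed test, which takes changes either way, passed there for the G1 and S lists (adjusted p = 0.00628 each) but not for G2M (0.086). In the other comparisons it passed for all 3 lists (highest adjusted p = 0.000183). It does not set a list against other genes, so these results are not particular to the lists.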

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

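Apart from the search for genes lower in control library 5, most tests here were chosen only after the results they bear on had been seen. These were the tests of the controls' division, of a wrong label, of depth and of other groupings of the samples. The slope with divided DN libraries was planned before the data were examined, but its criterion as a test of shared DN libraries was set afterwards. A library stood apart from the other 5 of its group in 15 of the values examined (54 groups of 6 libraries, gap over range above Dixon's 95% critical value). Chance exceeds that value in about 5% of groups of normally distributed values. Many groups here hold skewed CPM of identifiers picked for large changes, so the 15 cannot be set against this rate.

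The printed identifiers gave 7 of these values. ENSMUSG00000086503 stood at 0.839 CPM in control library 4, while the next control held 1405 CPM, and at 1.45 CPM in DN library 1 (next 0.834). ENSMUSG00000029368 stood at 5999.8 CPM in control library 5 (next 70.4) and at 2.08 CPM in treated library 1 (next 9.22). ENSMUSG00000094075 stood at 78.9 CPM in DN library 4 (next 10.5), and ENSMUSG00000116207 at 20.03 CPM in DN library 6 (next 65.7). ENSMUSG00000096715 stood at 0.252 CPM in control library 1 and at 0 in the other controls. Control library 4 also stood apart by its TMM factor (1.04), its position on the second principal component (-54.2), and its mean log2 CPM over the S list (4.32) and the G2M list (3.25). DN library 5 had a TMM factor of 0.886, treated library 1 a mean of 3.86 over the S list, control library 5 held 93 identifiers that were high in it alone, and DN library 2 held 2 such identifiers.

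The all-or-none division of the controls coincides almost wholly with the comparison of DN with Ctrl. Of its 25 identifiers, 4 had at most 1 count in each of the 5 controls and 734 to 3794 in each of the other 13 libraries, control library 4 included, and ENSMUSG00000086503 ran the other way. Presence or absence in both directions is what sex-linked genes would give between females and males, but without names this could not be tested. A candidate explanation is that these 5 animals differ from the other 13 in sex or genetic background, which the labels do not give, and that this accounts for part of the DN versus Ctrl calls. Against control library 4 alone, 986 genes were called between DN and Ctrl, within the 788 to 1111 called against any other single control, and that library lay at 0.227 on a scale from the other controls (0) to DN (1), above the highest other control (0.117). Because a single control lies on that side, the diet and STZ cannot be told apart from such a difference; a wrong label on control library 4 is argued against by its highest position of 0.281 on that scale over 10 divisions of the other controls, where a DN or treated library would lie near 1.

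The 93 identifiers in control library 5 were at 5 CPM or more and over 10-fold higher than in every other library, and they made up 1.002% of its counts. No other library held more than 2 such identifiers. A candidate explanation is RNA of another tissue in that library, which predicts additions without losses. Among identifiers at 5 CPM or more in every other library, 0 were over 10-fold lower in library 5 alone. This search was made for no other library, and other causes of added transcripts could give the same result, so the 0 does not decide. Of the 27 that were tested, 24 were called lower in DN, so that such genes stand among the DN versus Ctrl calls. No biological explanation was tested, and without names the tissue stays open.

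In these libraries the Treat minus DN difference rose with the DN minus Ctrl difference across genes in all 20 divisions. Shared DN libraries would push the slope below 0, and the lowest slope with these libraries divided was 0.0544; lower depth of the treated libraries is argued against by a slope of 0.0958 after thinning all libraries to the smallest total. An effect of TSK, or a difference in severity between the DN and treated animals before treatment, stays open, and neither was tested. Exact tests of 6 against 3 libraries, on the score along the model's direction, fell below 0.05 in 1 of 20 divisions. That of 6 against 6 on the first principal component, an axis these libraries helped to set, passed (exact permutation test, adjusted p = 0.0216). A displacement of the treated libraries along the DN effect is therefore a hypothesis about these animals and may not hold in others.

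For DN versus Ctrl, 1 of 100 splits of the libraries, the real one, gave as many as 6202 genes, and the highest other split gave 1394. This is the smallest share that 100 splits can give, so a chance split is an unlikely account of the count. For Treat versus Ctrl it was likewise 1 of 100, with 8629 genes and 2215 in the highest other split. Neither result tells the model apart from the all-or-none division of the controls. For Treat versus DN, 2 of 100 splits, the real one and 1 other, gave as many as 268 genes. That share is under 0.05, but an arbitrary split exceeded the real one, so chance is not excluded. The other such split called 558 genes with DN libraries 1, 2, 4 and 6 and treated libraries 2 and 5 on one side, which points to a structure among these 12 libraries that the groups do not describe, and this split called more genes than the real grouping did.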

How the results depend on the processing

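The values under library totals, with control library 4 left out together with another library, with thinned counts, with 1 member of near-identical pairs removed and with the controls' division as a covariate were added after the data had been seen, as were the cell-cycle lists under every setting; the other alternatives were planned. The planned tests of the fixed gene lists were not run, because their symbols could not be matched to the identifiers. No printed fold change, list call or slope that passed its test changed sign. The balance of directions did turn with library totals: the share of higher genes went from 38.4% to 84.4% of the Treat versus DN calls and from 52.5% to 48.9% of the DN versus Ctrl calls. This follows from the TMM factors, whose log2 ratio was 0.132 for Treat over DN and -0.029 for DN over Ctrl; which scaling is nearer the RNA content was not tested. With RLE size factors and with the stricter filter every count stayed within 1.5 times of its main value. The counts for DN versus Ctrl and Treat versus Ctrl stayed within 1.5 times of 6202 and 8629 except with a 2-fold minimum (1724 and 2441, which restricts by construction) and with the division of the controls as a covariate (986 and 1862, which leaves 1 control as reference). With each library left out they ranged from 5103 to 6936 and from 7909 to 8929. The 268 genes of Treat versus DN became 799 with DESeq2, 119 without a filter, 115 with only the 12 libraries compared, 737 with limma voom, 70 with a 2-fold minimum, 775 with library totals, 593 without control library 4 and treated library 1, and 97 to 446 with each library left out. In these same settings, the 52 genes called in opposite directions became 165 with DESeq2, 21 without a filter, 154 with limma voom, 5 with a 2-fold minimum, 139 with library totals and 121 without that pair of libraries (18 to 78 with each library left out). The 90 called in the same direction became 231 with DESeq2, 44 without a filter, 36 with only the 12 libraries, 262 with limma voom, 20 with a 2-fold minimum, 162 with library totals and 208 without that pair (42 to 162 with each left out). Apart from the 2-fold minimum and the library totals, the cause was not tested. Libraries whose removal moved the same-direction count by over 1.5 times were control 6 (57), DN 1 (53), DN 2 (49), DN 4 (42), DN 6 (54), and treated 1 (162), 3 (47) and 6 (57). For the opposite direction they were control 6 (31), DN 2 (22), DN 4 (18), DN 6 (28), and treated 3 (25) and 6 (34). The slope of 0.0958 was 0.0713 to 0.131 with each control or treated library left out, the highest without treated library 1.

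The replicate numbers do not pair the libraries: 2 of 18 same-numbered pairs had deviations correlated above 0.1 (range -0.189 to 0.185), and in 2 of 18 pairs the first library correlated best with its own number. With the number as a block, 117 genes were called between Treat and DN, 25 in the opposite and 50 in the same direction as in DN versus Ctrl.

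Of 239 values of the printed identifiers under alternatives, 209 kept their call and 30 lost it, 7 and 18 of them for the 2 identifiers that rose under treatment; DESeq2 gave no adjusted p for ENSMUSG00000029368. Of 198 values of the cell-cycle lists, 2 lost a call and 7 gained one. Of 216 values of library measures, 5 lost and 5 gained one. In simulated data for Treat versus DN, edgeR recovered 44.8%, limma voom 46.3% and DESeq2 53.7% of 67 genes changed 1.5-fold, so that changes of this size are often missed.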

Other observations

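The counts of genes by rule and by expression level and the correlations of libraries were chosen after the data had been seen. By a rule of at most 1 count in every library of one side and at least 100 in every library of the other, 1 identifier was absent from the 6 controls and present in the 12 DN and treated libraries, none was the reverse, and none set DN and treated libraries apart. More genes had a count in DN (26653 ± 529) than in Ctrl (25960 ± 332; SD, n = 6), a difference that passed the exact permutation test (p = 0.0325) but not its adjustment over 12 tests (adjusted p = 0.0649). Among the 1579 genes at 100 CPM or more, 637 were called lower and 304 higher in Treat than in Ctrl, and 376 lower and 300 higher in DN than in Ctrl. The difference between these proportions was not tested. All balances by expression level, those of Treat versus DN included, were computed with TMM factors only. With library totals 64.5% of all Treat versus Ctrl calls were higher, so these balances may depend on the scaling.

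Across groups, the libraries whose deviations from their group means correlated most were control library 4 and treated library 1 (r = 0.287 across genes), followed by control library 1 and treated library 2 (r = 0.242). The labels give no batch, cage or date.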
